A study of Homo sapiens with 109 samples.

How the data were processed

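RNA was measured in cultured and sorted prostate CAF cells as 108 Fluidigm C1 single-cell libraries in 2 processing batches and 1 10x Chromium library. Per the labels, C1 capture sites without exactly 1 cell and cells stained by ethidium homodimer-1 had been left out. The deposited C1 values are raw read counts per Ensembl gene ID and cell, without molecular identifiers, and the deposited 10x values are UMI counts per gene and barcode, with barcodes already selected as cells. The authors list the build GRCh38.p3, FastQC 0.11.3, TopHat2 2.1.0 and HTSeq 0.6.1, and Cell Ranger and Seurat without a version, and state no role for any of them.

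The C1 table held 57992 genes and that of 10x held 33694, from which 517 and 106 genes were left out (XIST and Y-linked genes). The C1 gene IDs took 33521 names from the 10x file and 24141 from GENCODE release 29, and 330 stayed unnamed. The C1 table lists 37 mitochondrially encoded genes, all at 0 reads. It also holds 1 column with no sample, which was not used. C1 cells needed at least 100000 reads on genes and 2000 genes with a read, and 10x barcodes at least 1000 genes and at most 10% mitochondrial UMIs. Scrublet, run through scanpy with seed 0, marked 1 barcode, which was left out, leaving 3017 cells and 131967806 UMIs. Scrublet simulates doublets from the data, so doublets of like cells escape it.

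Levels are UMIs per 1000000 UMIs (UPM) with exact Poisson intervals, and shares of cells have exact (Clopper-Pearson) intervals, at the 95% level. For shares, 10x cells were drawn down at random to 23000 UMIs (279 cells were too shallow) and C1 cells, for co-detection, to 549000 reads (8 and 3 too shallow). The floor for a count of 0 is 3 counts. Variance over mean was taken over genes with a mean of at least 0.5 UMI. Clustering used values scaled to 10000 UMIs and logged, 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.5. A cluster took a cell type's name when at least 3 of its markers, and at least 0.5 of those seen, were 2-fold over the other cells, a rule set after the data were seen. C1 batches were compared by the mean and SD over cells of log2(CPM + 1), where CPM is counts per 1000000 counts of a cell, and a list by the log2 of its summed CPM. C1 and 10x were compared by mean CPM with equal weight per cell, in genes with a count in both tables. Coherence is the median pairwise Spearman correlation across cells of list members seen in at least 20% of cells, as a percentile among 10000 random lists matched on mean expression.

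The 39 gene lists, the comparisons, the filters and the rule for named genes were fixed before the data were examined. Some members of the fixed lists, among them cell type markers and the plotted genes, were named without a size rule. The other genes were named by size only. They are the 20 most abundant in 10x outside the fixed ribosomal protein and mitochondrial lists (RPSA, a ribosomal protein gene, is not matched by the list's name pattern), the 10 largest differences in each direction between C1 batches (genes with a read in at least 50% of cells of 1 batch) and the 10 largest ratios in each direction between C1 and 10x (CPM of at least 50, same sign in both batches). To these came 5 leading genes per cluster, the 15 most variable genes and 2 to 4 members of each list described. The genes in the plot of shares were picked from the fixed lists after their values were seen. No test was made between runs, because each run is 1 sample. The methods were tested on simulated data with known changes, where 80% of genes changed 4-fold, but 14% of those changed 2-fold, were among the 200 largest C1 batch differences. There, 1500 simulated cells of 1 profile gave 1 cluster. Those cells differed by sampling only, so this does not show that clusters of real cells are separate groups.

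Alternatives covered thinning, detection limits, cell filters, clustering settings, scaling, pseudocount, cell weights and gene length. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.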

Results

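Single cells of cultured and sorted prostate carcinoma-associated fibroblasts (CAFs), connective tissue cells found around a tumour, were profiled on 2 platforms. The Fluidigm C1 system gave 108 single-cell libraries, each deposited as 1 sample, in 2 processing batches of 72 and 36 cells. The 10x Chromium system gave 1 library with 3321 cell barcodes, in which RNA molecules are counted by unique molecular identifiers (UMIs). In C1 batch 1, 70 of 72 cells were kept, with 238831 to 2098448 reads on genes (median 784270) and a median of 8269.5 genes with a read. In C1 batch 2, 32 of 36 cells were kept, with 124320 to 2365962 reads (median 857299) and a median of 8355.5 genes. The 6 C1 cells left out had between 377 and 5240 reads. In the 10x library 3018 barcodes were kept, with 8639 to 137673 UMIs (median 42273), a median of 5655.5 genes and a median mitochondrial share of 3.80%. The 303 barcodes left out had a mitochondrial share above 10%, with a median of 19.8%. The labels name no donor and no culture, so each of the 3 runs counts as 1 sample, cells are not replicates, and no difference between runs was tested. Intervals are exact, at the 95% level, and cover counting error only.

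The 10x cells carried the RNA of matrix-producing, contractile fibroblasts. All 15 fibroblast identity genes had a UMI in over 50% of the 3017 cells analysed, and together they made up 10890 UMIs per 1000000 UMIs of the library (UPM; 10873 to 10908). COL1A1, which encodes a chain of type I collagen, stood at 1806 UPM (1799 to 1813), and COL1A2, its partner chain, at 1398 (1391 to 1404). All 11 contractile protein genes were likewise seen in over 50% of cells and made up 10304 UPM (10287 to 10322). Among them were TPM2, a tropomyosin, at 2526 UPM and TAGLN, an actin-binding protein of smooth muscle and myofibroblasts, at 1602. Of the 20 most abundant genes outside the fixed ribosomal protein and mitochondrial lists, the first were the ferritin chains FTL at 25914 UPM (25887 to 25942) and FTH1 at 22973 (22947 to 22998). They were followed by MALAT1, a noncoding RNA kept in the nucleus, at 19875 UPM. The other 17 were EEF1A1, LGALS1, TMSB10, TMSB4X, S100A6, GAPDH, B2M, TPT1, VIM, IGFBP5, NEAT1, ACTG1, ACTB, GNB2L1, MYL6, RPSA and SERF2, from 12699 UPM for EEF1A1 to 2626 for SERF2. Cytosolic ribosomal proteins made up 301427 UPM and the mitochondrially encoded genes 41466.

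Shares of cells were compared after every cell was drawn down to 23000 UMIs, which 2738 cells reached. THY1, a fibroblast surface protein, had a UMI in 93.4% of those cells (92.4 to 94.3), PDGFRA, a growth factor receptor, in 77.5% (75.9 to 79.0), and FAP, a surface protease used as a CAF marker, in 56.8% (54.9 to 58.7). ACTA2, the smooth muscle actin of myofibroblasts, had one in 98.5% (98.0 to 98.95). NR3C1, the glucocorticoid receptor, was seen in 59.2% of cells (57.4 to 61.1). Most markers of epithelium, endothelium and blood cells were rare, with some exceptions. EPCAM, an epithelial adhesion protein, had a UMI in 0.256% of cells (0.103 to 0.526) and PTPRC, carried by blood cells, in 0.292% (0.126 to 0.575). KLK3, the prostate-specific antigen, KRT5, a basal cell keratin, and PECAM1, an endothelial adhesion protein, had none in the 3017 cells, for which the floor of 3 counts allows a share of cells with a UMI of up to 0.0994%. The exceptions included the simple-epithelium keratins KRT18, with a UMI in 68.6% of cells (66.8 to 70.3), and KRT8, in 48.3% (46.4 to 50.2). They also included EGFL7 of the endothelial list, in 40.5%, and the lysosomal protein CD68 of the myeloid list, in 32.2%. No cell type lacking these genes was present to measure background from free RNA, so the shares are of cells with a UMI, not of cells expressing a gene. COL1A1 lies on chromosome 17 from 50183289 to 50201632, ACTA2 on chromosome 10 from 88935074 to 88991339, FAP on chromosome 2 from 162170684 to 162245151, and KRT18 on chromosome 12 from 52948871 to 52952901 (GRCh38).

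**Figure D1:**
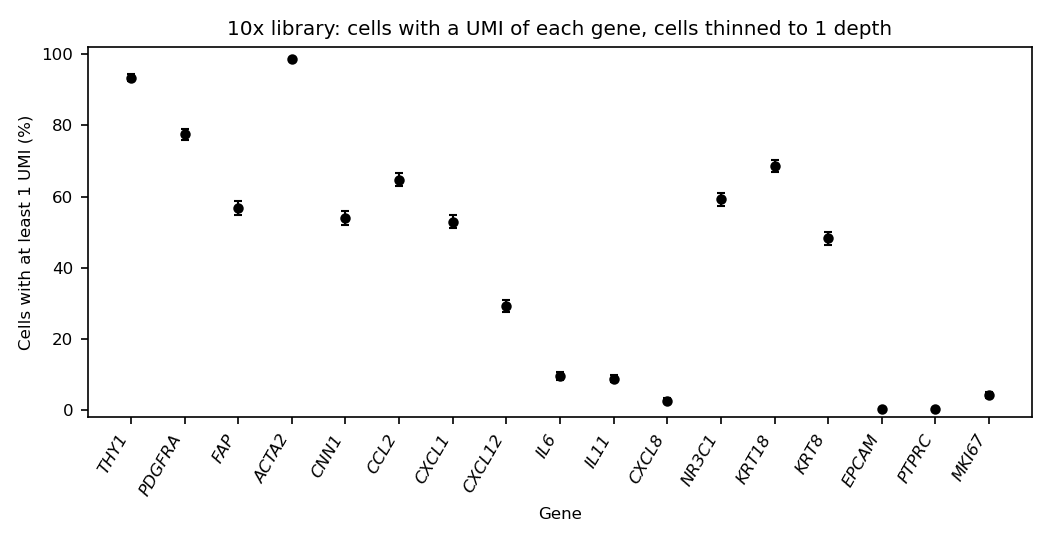
Share of 10x cells with at least 1 UMI (y axis, percent) for 17 genes of the fixed lists (x axis), after each of 2738 cells was drawn down to 23000 UMIs; points are shares and bars exact 95% intervals. ACTA2 and THY1 lie above 90%, CCL2, CXCL1 and FAP between 50% and 70%, and EPCAM and PTPRC under 1%.

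Chemokines and cytokines were carried by unequal parts of the cells. CCL2, which attracts monocytes, was the most widely seen, with a UMI in 64.7% of the thinned 10x cells (62.9 to 66.5) at 127.0 UPM. CXCL1, which attracts neutrophils, was seen in 52.9% (51.03 to 54.8) and CXCL12, the ligand of the receptor CXCR4, in 29.3% (27.6 to 31.04). IL6 was seen in 9.57% of cells (8.49 to 10.7), IL11 in 8.88% (7.84 to 10.0) and CXCL8 in 2.70% (2.13 to 3.38). At a limit of 1 UMI, CCL2 and CXCL12 were seen together in 498 cells, 0.959 times the product of their shares (0.884 to 1.04). The intervals of these ratios cover the count of cells with both genes and take the shares as fixed, so they do not test independence. CCL2 and IL6 were seen together 1.17 times as often as that product (1.02 to 1.33), and CXCL8 and CXCL1 1.46 times (1.10 to 1.88). When 2 UMIs were asked for in place of 1, the 3 ratios were 0.607 for CCL2 and CXCL12, 1.35 for CCL2 and IL6, and 2.87 for CXCL8 and CXCL1. The value near 1 for CCL2 and CXCL12 thus held at 1 UMI only. In the C1 runs CCL2 had a read in 98.6% of batch 1 cells and 96.9% of batch 2 cells, CXCL12 in 52.9% and 56.2%, and CXCL1 in 14.3% and 18.8%. All co-detection intervals of C1 pairs contained 1, which decides nothing on independence. CCL2 had a read in 61 of 62 thinned batch 1 cells and 28 of 29 in batch 2, so its ratios could hardly leave 1. Pairs without CCL2 rested on at most 10 cells with both genes. CCL2 lies on chromosome 17 from 34255218 to 34257203 and CXCL12 on chromosome 10 from 44370165 to 44386493.

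The genes that varied most between 10x cells, by the variance of thinned UMI counts over their mean, were the ferritin chains, a metallothionein, nuclear noncoding RNAs, contractile genes and mitochondrial genes. FTL had a variance 81.2 times its mean, MT2A, a metal-binding stress protein, 78.6 times, and MALAT1 64.7 times. FTH1 followed at 56.8 and IGFBP5, which binds insulin-like growth factors, at 55.4. The contractile genes ACTA2 and TAGLN had ratios of 23.6 and 22.1. The other 8 of the 15 genes named were MT-CO1, TMSB4X, MT-CO2, NEAT1, VIM, PTGDS, TUBA1B and MGP, down to 15.2 for MGP, an inhibitor of calcification. Over the 4292 genes ranked, the median ratio was 1.15, and counting error alone gives 1. This ratio grows with a gene's level, and the most abundant genes stand among the first.

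The 3017 cells of the 10x library fell into 8 clusters of 862, 679, 618, 409, 173, 166, 57 and 53 cells, of which 3 carried the markers of dividing cells. Clusters 5, 7 and 8 had enough cycling markers to be called cycling-like and together held 283 cells, 9.38% of the library (8.36 to 10.5). In cluster 7 all 15 cycling markers were at least 2-fold over the other cells, and the list stood at 28.96-fold. MKI67, a protein of dividing cells, had 175 UPM there (161 to 191), 112-fold over the other cells, and TOP2A, which untangles DNA, stood at 70.1-fold. In cluster 5 the same list stood 3.01-fold higher, with MKI67 at 2.97-fold and BIRC5, which acts in cell division, at 8.07-fold. Nuclear long noncoding RNAs were at 0.0427-fold in cluster 8; their lowest fold in any cluster was 0.628 when cells were drawn down to equal depth before clustering and 0.618 without the cells of cluster 8. Cluster 8 owed its name to 3 genes, BIRC5, TYMS and RRM2, which also lead its definition, and MKI67 was at 1.01-fold there. It had a median of 14074 UMIs per cell, 0.333 of that of the sample. Without cluster 8 the cycling-like share was 7.62%, and it was 3.65% in 3 other clusterings, with a resolution of 0.25, another seed or the chemokine lists left out. Metallothioneins were also higher in these clusters, at 3.27-fold in cluster 5, 3.66-fold in cluster 7 and 4.73-fold in cluster 8, with MT2A at 3.29-fold, 3.81-fold and 5.44-fold. Fibrillar collagens were lower, at 0.568-fold in cluster 5, 0.648-fold in cluster 7 and 0.159-fold in cluster 8.

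The other 5 clusters had too few of any cell type's markers for a name and differed in matrix, chemokine and contractile genes. Cluster 6 had 5 of the 11 myofibroblast markers seen at least 2-fold up, under the part asked for. Cluster 3 had 2 of the 4 inflammatory fibroblast markers seen at least 2-fold up, under the number asked for. Cluster 3, of 618 cells with 0.713 of the sample's median depth, was led by APOE and FABP3, which bind lipids, MGP, ADH1B and PTGDS, at 8.41-fold to 4.84-fold. It also had CXCL12 at 3.66-fold and CTSK, a collagen-degrading protease, at 3.42-fold, while CCL2 stood at 0.320-fold and metallothioneins at 0.387-fold. Nuclear long noncoding RNAs were at 1.49-fold there, the highest of the 8 clusters. The contrast did not come from clustering on those genes, since a clustering without the chemokine lists also gave a cluster, of 671 cells, with CXCL12 at 3.16-fold and CCL2 at 0.378-fold. Cluster 6, of 166 cells, was led by VTN, ACTA2, ASNS, ACTG2 and TUBA1A, at 3.75-fold to 3.25-fold. In it contractile proteins stood at 2.05-fold, the smooth muscle list at 3.02-fold and heat shock proteins at 1.82-fold, with HSP90AA1 at 3.16-fold. The smooth muscle list, at 1802 UPM against 597, was mostly ACTG2, at a mean of 1729 CPM per cell against 527. Its rise thus largely restates a leading gene, and ACTA2 and ACTG2 belong to the contractile list too. Cluster 4 was led by EMX2OS, EMX2, a homeobox transcription factor of the urogenital tract, SAMD5, S100A4 and CELF2, at 8.52-fold to 3.38-fold. Cluster 2 was led by VEPH1, SCN9A, MGAT5, GALNT5 and F2RL2, at 2.77-fold to 2.28-fold. Cluster 1, the largest, was led by CCL11, AKAP6, TSTD1, MT1F and FIBIN, all under 2-fold, and had KRT18 at 1.57-fold, against 0.202-fold in cluster 4. The cycling-like clusters were led by TROAP, PTTG1, TK1, BIRC5 and CDKN3 (cluster 5), KIF18B, ESCO2, HIST1H1B, FAM111B and NUF2 (cluster 7), and BIRC5, RRM2, PBK, PTTG1 and TYMS (cluster 8). Leading genes define the clusters and are not a result. Their folds, and the 2-fold rule for names, use mean CPM with equal weight per cell, while other cluster folds use summed UMIs. Over 13 other clusterings of every cell, the median overlap (Jaccard index) with the best-matching cluster was 1 for clusters 7 and 8 and 0.570 to 0.856 for the others. In the clustering that matched each least, it was 0.0884 for cluster 6, 0.109 for cluster 5, 0.297 for cluster 4 and 0.982 for cluster 7. It was 0.0618 for cluster 8 when cells were drawn down to equal depth first, which 11 of its cells could be.

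**Figure D2:**
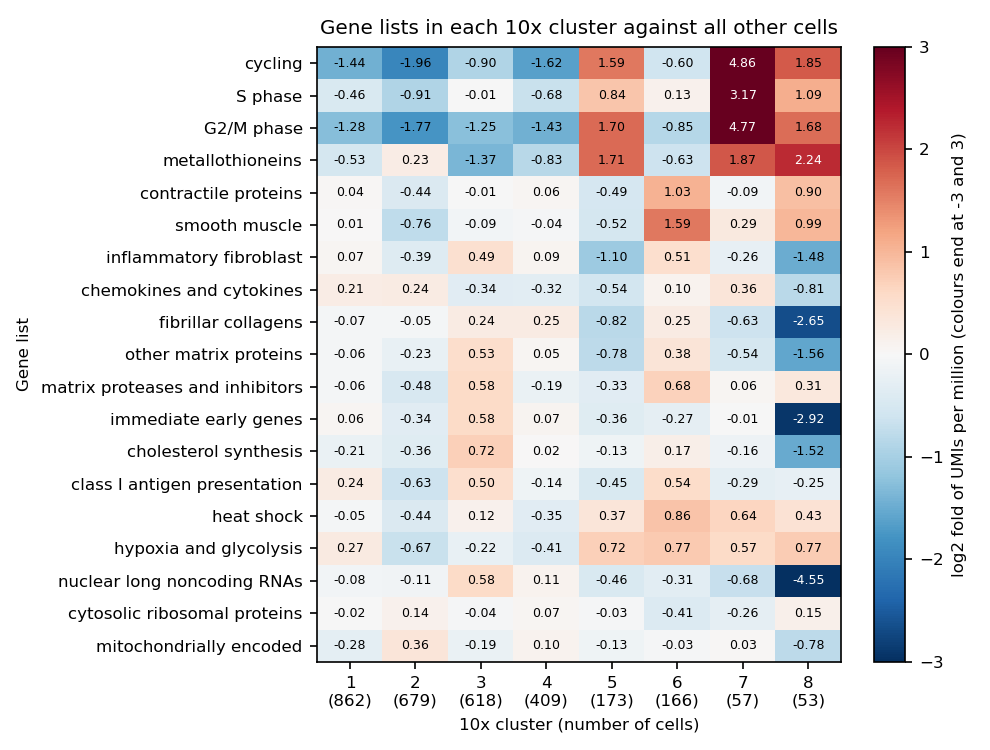
The log2 fold of 19 gene lists (y axis) in each of the 8 clusters of the 10x library (x axis, with the number of cells), as UPM of the list over that of all other cells; numbers give the values and colours end at -3 and 3. The cycling list is at 28.96-fold in cluster 7, metallothioneins at 3.27-fold to 4.73-fold in clusters 5, 7 and 8, contractile proteins at 2.05-fold in cluster 6, and the nuclear long noncoding RNAs at 0.0427-fold in cluster 8.

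Between the 2 C1 batches, batch 2 was higher in targets of the growth factor TGF-beta and in genes of hypoxia and glycolysis, and lower in immediate early genes. Differences are batch 2 minus batch 1, of the mean over cells of log2(CPM + 1), in 70 and 32 cells. The TGF-beta targets differed by 1.46, which is 1.66 times the SD between cells, and 6 of the 7 members ranked were higher by at least 1. Among them were TGFBI, an extracellular matrix protein, at 7.24 ± 2.41 (SD) in batch 1 and 10.08 ± 1.70 in batch 2, and SMAD7, an inhibitor of TGF-beta signalling, which differed by 2.30. Hypoxia and glycolysis genes differed by 0.88 (1.64 SD), and all 10 members ranked were higher, 3 of them by at least 1, among them PDK1 by 1.88 and BNIP3 by 1.67. Matrix proteases and inhibitors differed by 1.23 (1.31 SD), with the protease inhibitor TIMP1 at 11.08 ± 1.30 and 12.78 ± 1.11, and by 0.21 without TIMP1. Immediate early genes, which are switched on within minutes of a stimulus, differed by -2.04 (-1.11 SD). All 9 members ranked were lower, 3 of them by at least 1, with EGR1, a transcription factor, at -3.45 and FOS at -2.81. These 4 of the 39 lists differed by more than 1 SD between cells, against 1 list with every cell in the table and 7 with summed counts. With every cell, the TGF-beta targets differed by 0.71 and the hypoxia and glycolysis genes by 0.49.

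Another 11 lists differed by 0.5 to 1 SD. S phase genes were higher in batch 2 by 1.13, with all 16 members ranked higher, chemokines and cytokines by 1.12, growth factors by 0.44, heat shock proteins by 0.43 (-0.0388 with every cell in the table) and cytosolic ribosomal proteins by 0.17. Chemokines and cytokines had 5 members higher and 1 lower, heat shock proteins 4 and 3, and ribosomal proteins 62 and 20. Growth factors had 6 higher and 3 lower, and by at least 1 these were 1 and 3. Lower lists were NF-kB targets at -1.18, smooth muscle at -1.02, p53 and senescence at -0.84, nuclear long noncoding RNAs at -0.69, interferon response at -0.66 and class I antigen presentation at -0.49. The 24 remaining lists differed by less than 0.5 SD or, for the mitochondrially encoded genes, could not be compared. Among them, G2/M phase genes were higher by 1.08, with all 19 members ranked higher, and cycling genes by 1.01, with all 15 higher. These shifts are near that of S phase genes, but the SD between cells was 3.15 and 3.28, against 2.06. Among single genes, the largest differences in batch 2 were those of NPR3, a receptor that clears natriuretic peptides (3.73), HSD11B1, which activates glucocorticoids (3.10), ID3 (3.04), POSTN, a matrix protein of activated fibroblasts (2.96), TGFBI (2.84), TFPI2 (2.80), IL33 (2.70), IGFBP3 (2.66), CGA (2.64) and IL11 (2.63). The largest in the other direction were those of SCD, a fatty acid desaturase (-4.96), RASSF3 (-4.24), F3, which starts blood coagulation (-4.19), TNFAIP2 (-4.04), RASSF2 (-3.94), SCN9A (-3.54), EGR1 (-3.45), FLCN (-3.43), OXTR (-3.36) and SCUBE3 (-3.32). SCD had a read in 70 of 70 batch 1 cells and in 26 of 32 batch 2 cells, and IL11 in 12 of 70 and 24 of 32. The difference was over 1.5 times smaller for 12 of these 20 genes with log2(CPM + 10) and for 8 with summed counts. With every cell in the table, chemokines and cytokines differed by 0.43, growth factors by 0.09 and interferon response by -1.14. The median difference over the 8406 genes ranked was 0.01. With 1 run per batch and no donor labels, cells and processing cannot be told apart. NPR3 lies on chromosome 5 from 32689070 to 32791724, SCD on chromosome 10 from 100347124 to 100364834 and TGFBI on chromosome 5 from 136028895 to 136063818.

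**Figure D3:**
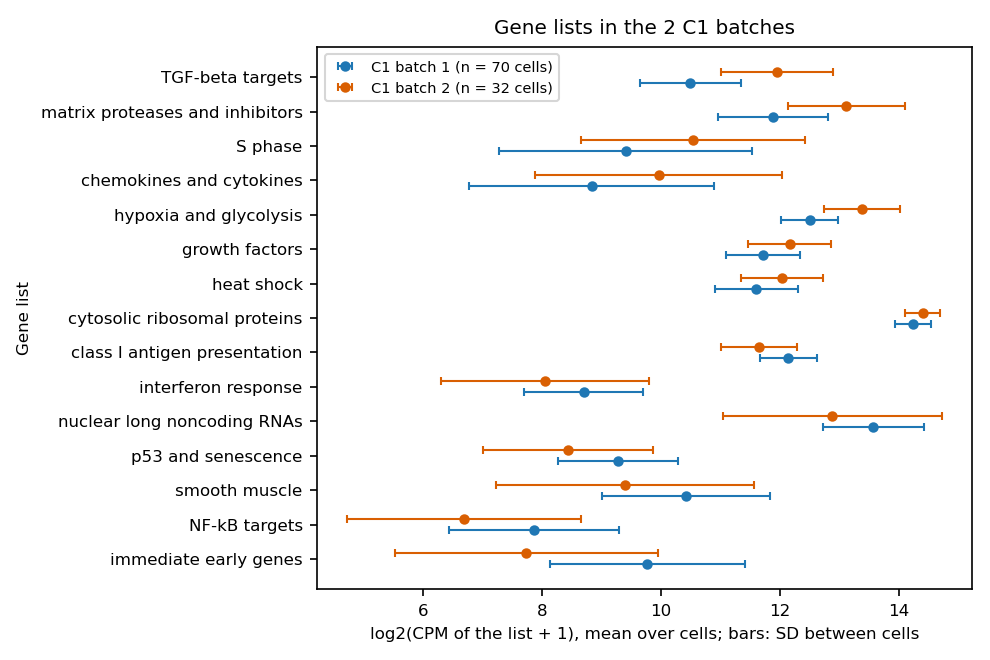
The 15 gene lists that differ between the C1 batches by more than 0.5 SD between cells (y axis); points are the mean over cells of log2 of the list's CPM plus 1 (x axis), in 70 cells of batch 1 and 32 cells of batch 2, and bars the SD between cells. The TGF-beta targets lie at 10.50 and 11.95, and the immediate early genes at 9.78 and 7.74.

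Cell cycle genes were higher in the C1 runs than in the 10x library, and ribosomal protein genes were lower. The cycling list had 3676 CPM in C1 batch 1 and 4877 in batch 2, against 118 CPM in the 10x library, log2 ratios of 4.96 and 5.37 with all 15 members higher in both batches. The G2/M phase list stood at 4.57 and 4.99 and the S phase list at 3.31 and 4.04. MKI67 had a read in 74.3% of batch 1 cells (62.4 to 84.0) and 71.9% of batch 2 cells (53.3 to 86.3), and in the 10x library a UMI in 5.63% of cells at full depth. Reads and UMIs were not matched in depth here, so these are not shares of dividing cells. Growth factors, at 2.20 and 2.69, were also higher in C1. Other matrix proteins stood at 1.36 and 1.42, near the medians of 1.46 and 1.34 for the 2370 genes with the longest exons. Cytosolic ribosomal proteins were lower in C1, at -3.92 and -3.75, with 80 of 84 members lower in both batches. Metallothioneins, at -1.18 and -1.26, and class I antigen presentation, at -0.54 and -0.98, were lower as well. Fibroblast identity genes differed by 0.75 and 0.54 and contractile proteins by -0.28 and -0.56. CPM are parts of a total, of which ribosomal proteins held 298993 in 10x but 19716 and 22168 in C1. With all genes split into 4 groups by exon length, group medians ran from -0.25 to 1.46 in batch 1 and from -0.09 to 1.34 in batch 2. Fibroblast identity lay within these ranges, growth factors above them, and contractile proteins and class I antigen presentation below them. Apart from ribosomal proteins, no list was matched on length between C1 and 10x.

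The 10 genes highest in C1 were MTRNR2L10 (10.81), NECAB1 (8.45), PABPC3 (8.40), HAS2, which makes the matrix sugar hyaluronan (7.77), MTRNR2L12 (7.52), TRIM59 (6.93), and the mitosis genes CENPE (6.85), CASC5 (6.75), BUB1 (6.71) and CKAP2L (6.55), as the smaller log2 ratio of both batches. MTRNR2L10 and MTRNR2L12 are nuclear genes that resemble mitochondrial ribosomal RNA, and the C1 table has no read on any of its 37 mitochondrially encoded genes. The source of the C1 reads on MTRNR2L10 and MTRNR2L12 was not tested, so their ratios may not show the level of these genes. The 10 highest in the 10x library were C4orf48 (-8.89), TPGS1 (-8.63), RPS27 (-8.45), PPDPF (-8.37), ARL6IP4 (-8.23), SOD3, an extracellular superoxide dismutase (-8.08), A1BG (-7.90), RPS9 (-7.69), MAP1LC3A, an autophagy protein (-7.69), and MRPL23 (-7.59). TPGS1 and MAP1LC3A had no read in batch 2, so their ratios there use the floor of 3 counts. Across 9510 genes, which are not independent replicates, the rank correlation was 0.900 between the C1 batches, 0.476 between batch 1 and 10x, and 0.456 between batch 2 and 10x. It was 0.706 and 0.691 against 10x when genes down to 1 CPM were taken in. The ratio of C1 over 10x went with the length of a gene's exons (rank correlation 0.309 and 0.236), with a median log2 ratio of -0.25 and -0.09 in the 2371 genes with the shortest exons and 1.46 and 1.34 in the 2370 with the longest. C1 counts reads along transcripts and 10x counts molecules, and platform, culture and batch cannot be told apart here. HAS2 lies on chromosome 8 from 121612116 to 121641390, CENPE on chromosome 4 from 103105806 to 103198409 and RPS27 on chromosome 1 from 153990755 to 153992155.

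**Figure D4:**
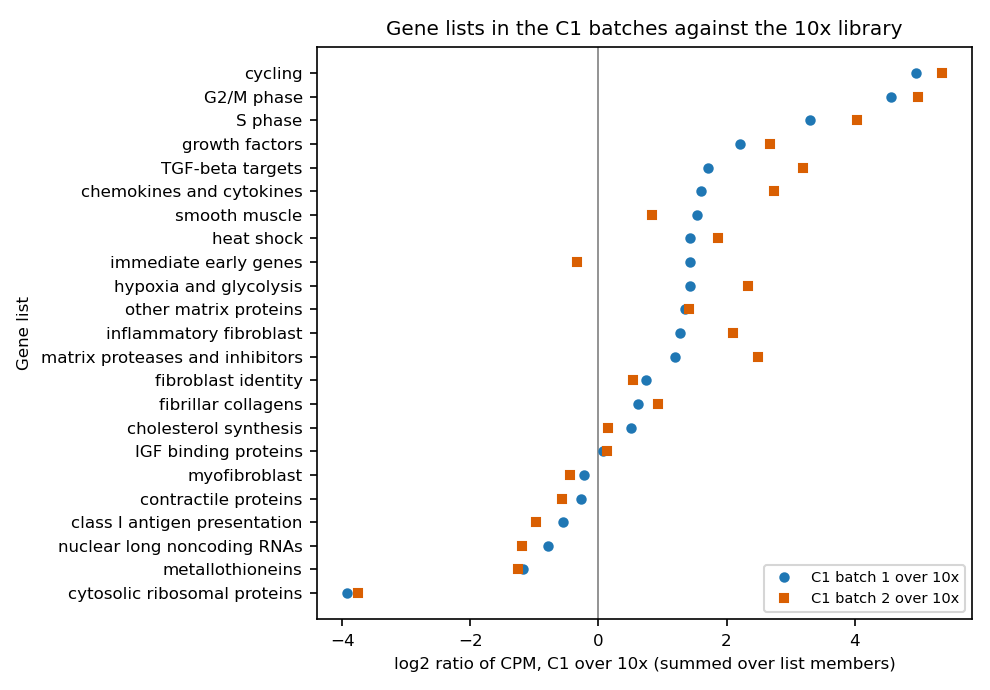
The log2 ratio of summed CPM in C1 batch 1 (circles) and C1 batch 2 (squares) over the 10x library (x axis), for 23 gene lists (y axis); the grey line marks equal levels. The cycling list lies at 4.96 and 5.37 and the cytosolic ribosomal proteins at -3.92 and -3.75.

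Genes of several functions rose and fell together from cell to cell in all 3 runs. Of the 24 lists that could be measured in every run, 12 had a median pairwise correlation across cells at or above the 95th percentile of random lists of the same size and level in all 3. Fibrillar collagens did so most clearly among matrix genes, with a median correlation of 0.385 in 10x, 0.474 in C1 batch 1 and 0.585 in C1 batch 2. Contractile proteins reached 0.416, 0.487 and 0.252, metallothioneins 0.263, 0.508 and 0.540, and immediate early genes 0.106, 0.170 and 0.209. The others were S phase, class I antigen presentation, cytosolic ribosomal proteins, fibroblast identity, hypoxia and glycolysis, myofibroblast, other matrix proteins and unfolded protein response. These lists share genes, so the 12 are not separate results. The myofibroblast list is the contractile list plus POSTN, and in 10x both were scored on the same 11 genes, at 0.416. Fibroblast identity shares collagens, DCN and LUM with the matrix lists. Cycling genes had 0.719 in C1 batch 1 and 0.642 in C1 batch 2, and too few of them were seen in 20% of 10x cells to be scored there. Chemokines and cytokines, scored on the members seen in at least 20% of cells, stayed under the 95th percentile, at 72.8 in 10x, 84.2 in C1 batch 1 and 45.7 in C1 batch 2. Inflammatory fibroblast genes stood at 13.2, 87.4 and 68.2. The genes that define 10x clusters 5, 7 and 8 were at the 100th percentile in both C1 batches, which did not enter the clustering. Many of them are cell cycle genes, and clusters 5 and 8 share BIRC5, PTTG1 and RRM2 among others. This largely restates the correlation of cycling genes and does not show these clusters as separate groups in C1. The genes that define cluster 3 stood at 98.2 and 40.2, those of cluster 6 at 76.0 and 75.9 and those of cluster 4 at 31.5 and 33.9.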

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

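The alternatives with thinned cells, chemokine lists left out or cluster 8 left out, the cycling-like share under other principal components and seeds, and the C1 against 10x named genes were chosen after seeing the data. The 20 genes named between C1 batches kept their direction in 140 of 140 recomputed values, and the lists in 104, with 1 reversed: heat shock was at -0.0388 when every cell in the table was used, against 0.43. Of these 15 lists, 5 (heat shock included) differed by over 1.5 times less and 2 by over 1.5 times more with every cell, and 2 less with summed counts, 1 with the stricter cell filter and 1 with size factors; interferon response ran from -1.14 to -0.36 and ribosomal proteins from 0.08 to 0.28. The number of C1 lists past 1 SD was 1 with every cell and 7 with summed counts, against 4. The 20 genes named between C1 and 10x kept their direction in 4 of 4 settings. The rank correlation with 10x was 0.706 and 0.691 with genes down to 1 CPM and 0.512 and 0.478 with C1 values divided by exon length, against 0.476 and 0.456. Genes of the fixed lists with a UMI in at least 50% of 10x cells numbered 79 when 2 UMIs were asked for, against 125, and the co-detection ratio of CCL2 and CXCL12 was then 0.607, against 0.959. The lowest fold of nuclear long noncoding RNAs in any cluster was 0.628 with thinned cells and 0.618 without cluster 8, against 0.0427. There were 4 clusters at resolution 0.25 and 14 at resolution 1.0, against 8. The cycling-like share, 9.38%, was 3.65% at resolution 0.25, with seed 2 and with chemokine lists left out, 12.8% with 50 principal components, 10.9% with the Scrublet call kept, 7.46% without the cells of cluster 8 and 7.62% with cluster 8 not counted. Lists coherent in all 3 runs numbered 11 to 14, against 12. Of the shares of cells with a UMI, 54 recomputed values lay outside their interval and 31 inside; these shares depend on depth. The detection limit and the cell counts act by construction, and so does leaving out cluster 8 on the lowest fold of nuclear RNAs. Thinning kept only 11 of the 53 cells of cluster 8. Every cell in the table brings back the C1 cells left out, which had 377 to 5240 reads. How far these 2 points account for the shifts was not tested, nor was the cause of the others.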

Other observations

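Tests of leaking cells and mitosis in cluster 8, of 1 dominant gene in the C1 lists, and of gene and principal transcript length in ribosomal protein genes were chosen after the results were seen; apart from mitosis in cluster 8, no biological explanation was tested. Several groups of stress and metabolic genes also differed between 10x clusters. Hypoxia and glycolysis genes stood at 1.71-fold in cluster 6, 1.70-fold in cluster 8, 1.64-fold in cluster 5 and 1.48-fold in cluster 7, against 0.630-fold in cluster 2. Class I antigen presentation stood at 1.42-fold in cluster 3 and 1.45-fold in cluster 6, against 0.647-fold in cluster 2. Cholesterol synthesis genes were highest in cluster 3, at 1.65-fold, as were immediate early genes among the 8 clusters. Mitochondrially encoded genes were at 1.29-fold in cluster 2 and 0.584-fold in cluster 8. In the C1 table, 404 nuclear copies of mitochondrial genes held 31375.5 CPM in batch 1 and 28646.5 in batch 2. The 10x data list only 11 such genes, at 23.6 UPM, so these totals cover different genes and cannot be compared. The C1 table had no read on its 37 mitochondrially encoded genes, and the source of its reads on the nuclear copies was not tested.

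Cluster 8 of the 10x library was low in the nuclear noncoding RNAs MALAT1 and NEAT1. Low depth was argued against, as the 128 cells of other clusters with at most 19167 UMIs, the upper quartile of cluster 8, had a median of 32679 UPM at a median depth of 15227 UMIs, against 14074 in cluster 8. Mitosis like that of cluster 7 was argued against by the G2/M phase list at 0.189 times cluster 7 (0.173 to 0.206), with 17 of 19 members under 0.25 times but BIRC5 at 0.881 and PTTG1 at 0.830, although the list was at 3.21-fold over the other cells. Free RNA of 1 pool as the whole content was argued against by 86.7% of 422 genes that varied between these droplets beyond the 99th percentile of droplets simulated from 1 pool. Barcodes above 10% mitochondrial UMIs had been left out before clustering, so leaking was judged only among the barcodes kept. There, a median mitochondrial share of 2.08% in cluster 8, against 3.80% in all cells, argued against leaking cells. A candidate explanation that stays open is that these droplets may lack most of a nucleus, as 5 other nuclear RNAs were at 0.112 times the other cells (0.0722 to 0.165) while the cytoplasmic SNHG8 and ZFAS1, the 2 measured of 5 planned, were together at 1.05 times. The nuclear value rests mostly on MEG3, with 16 of the 25 UMIs in cluster 8, at 0.105 times. TUG1 was at 0.194 and KCNQ1OT1 at 0.0328 times, while PVT1 and MIAT, with 1 and 0 UMIs, were barely measured. Fibrillar collagens were also low in cluster 8, so low levels were not particular to nuclear RNAs.

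The 4 lists that differed by more than 1 SD between C1 batches kept at least 0.966 of their difference when cells were drawn down to equal reads. The batches were close in depth before that (median 784270 and 857299 reads), so thinning could change little and decides little on read depth. Genes of like length showed at most 0.0241 of it and genes of like GC content at most 0.0408. For matrix proteases and inhibitors, 1 dominant gene may account for most of it, since the list kept 0.170 of its difference without TIMP1. The other 3 lists kept at least 0.690 without their most abundant gene. Batch and culture cannot be told apart.

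Ribosomal protein genes were lower in C1 than in 10x. They stayed lower than other genes of like length, by a median log2 difference of -3.73, like principal transcript length, at -2.98, and like GC content, at -4.12, which argues against each as the whole cause. Loss of reads shared with processed pseudogenes may contribute, as the ratio fell with the number of named pseudogenes among ribosomal protein genes (Spearman rho -0.380 across genes, which are not independent replicates). Among other genes, those with at least 3 pseudogenes had a ratio higher than matched genes with none, by a median of 0.19. No such fall was thus seen outside ribosomal protein genes, but quartiles of -1.06 and 1.28 are too wide to decide. Chemistry and culture stay open, as untested.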
